A study of Mus musculus with 8 samples.

How the data were processed

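RNA sequencing was done on hematopoietic stem cells from mouse bone marrow, sorted as CD48-negative, CD150-positive cells within the lineage-negative, Sca-1-positive, Kit-positive (LSK) fraction. There were 4 libraries labelled DekCon and 4 labelled DekTg, which are genotype names; the labels say nothing more about either genotype. Per the labels, total RNA was extracted with a miRNeasy kit, reverse-transcribed and amplified by Geo-seq, a protocol made for small numbers of cells, and turned into libraries with a tagmentation kit. Per the submitters' processing notes, Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq, DESeq2 and build mm10 were used. The role and order of these tools, the annotation and the strand setting are not given in the sources used here.

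The deposited values are a signal per gene and library that the table's name calls FPKM, but they do not behave as FPKM. Within a library, the values of 52218 of 52224 genes are whole multiples of a single step, within 5.0e-05 reads. The reciprocals of the steps equal DESeq2's median-of-ratios size factors computed from the recovered reads, with a relative gap of at most 4.4e-05. The values were therefore read as gene counts that the authors divided by 1 size factor per library, and are called normalized read counts here. They are scaled for depth and not for gene length, so levels of different genes cannot be compared as molar amounts. The test fixed before the data were examined assumed FPKM; it was kept, since it fits any normalized value on a log scale.

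Of 417792 values, 25 in 6 genes were not whole multiples of the step (tolerance 0.001 reads), so 99.99% of values came out whole. These genes are Dek (4 values), Cdc20 (4), Cdk1 (6), Fos (3), Ifit2 (7) and Csf2 (1). The sources used here do not say how these values arose. Counts of genes are therefore also given without these 6 genes.

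Recovered reads per library ranged from 2.53 to 4.10 in units of 1000000. Without molecular identifiers, reads from amplified cDNA are not independent molecules, so read numbers show counting error only in part. A gene was tested when its value was at least 1 in at least 4 of the 8 libraries, which left 37414 genes. That value is 1 read in 3 libraries and 2 reads in the other 5. Differences are on the scale log2(value + 1), DekTg minus DekCon, and understate the change of low genes. The main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend and no covariates, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Gene lists (34 tested, fixed before the data were examined) were compared with all other genes by limma's camera with a preset correlation of 0.01, and again with an estimated correlation. Limma's fry was used for a directional test of each list. The Dek level, the sort markers and 4 library measures were compared by two-sided exact permutation tests (scipy). On simulated reads for the DekTg versus DekCon comparison (23065 genes), the limma test recovered 100% of 4-fold changes and 92% of 2-fold changes, with 6 false calls. The changed genes were drawn from well-expressed genes only, their spread followed the trend with level (median dispersion 0.0348), and the libraries were independent. Recovery in the real data can be lower, so genes not called may still differ by 2-fold. For example, Gp5 at a log2 fold change of -1.13 did not pass (limma adjusted p = 0.639).

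The rule for named genes was also fixed beforehand. Dek comes first, followed by genes past the threshold whose groups do not overlap, leaving out predicted genes and immunoglobulin segments, up to 12 per direction by log2 fold change. Where fewer qualified, up to 6 per direction were filled with non-overlapping genes of smallest unadjusted p. Each list gives its members past the threshold, or its 2 members of smallest p as values (1 of them for stem cell identity). Sort markers and sex-linked transcripts are given as values. Each list gives at most 4 such members per direction. Nek2, Ifit3, Hbb-bt and Pax5, which pass over a list alone, Slc4a1, Klf1 and the immunoglobulin segments and constant genes lie outside the rule and were chosen after their values were seen, as were the neighbours of Phactr2. Of 759 list symbols, 758 were in the table and 755 were tested. Gene positions are from GENCODE M21 on GRCm38, which mm10 names.

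Alternatives fixed beforehand were other pseudocounts, filters, scalings and limma options, the replicate number as a block, and leaving out each library. Other alternatives were added after seeing the data: leaving out the 6 genes, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads without those genes, DESeq2 also without independent filtering, averaging libraries 1 and 4 of each group, and a term for libraries 1 and 4 against 2 and 3. The labels do not say that the libraries come from separate mice. P-values therefore measure the spread between these samples, which may be technical.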

Results

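The series concerns DEK, a chromatin-associated protein, in relation to replication stress and to the function of hematopoietic stem cells in Fanconi anemia, an inherited failure of DNA crosslink repair. The comparison analysed here asks which transcripts differ between sorted stem cells of DekTg and DekCon mice. Recovered reads averaged 3.39 ± 0.67 in DekCon and 3.06 ± 0.41 in DekTg, in units of 1000000 reads (SD, n = 4 each). The number of reads did not separate the groups (two-sided exact permutation test, p = 0.457, adjusted p = 0.61 over 4 library measures). The mitochondrial share of reads was 2.98 ± 0.31% in DekCon and 3.47 ± 0.17% in DekTg (exact permutation p = 0.057, adjusted p = 0.229).

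Dek itself was listed higher in all 4 DekTg libraries. Its normalized read count was listed at 511 ± 100 (SD, n = 4) in DekCon and 2392 ± 403 (SD, n = 4) in DekTg, a ratio of means of 4.68. The log2 fold change was 2.23 (SE 0.16, limma adjusted p = 1.14e-06). A two-sided exact permutation test gave p = 0.0286, the smallest this design allows. Dek lies on chromosome 13 from 47084775 to 47106201 on the minus strand, and overlaps Kdm1b on the other strand. All 4 DekTg values of Dek are among the 25 values that are not whole numbers of reads, and the 4 DekCon values are whole. The ratio, the fold change and both p-values therefore rest on values that are not read counts. The size of the Dek difference cannot be taken as measured.

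In all, 13 of 37414 genes passed the threshold, 10 higher and 3 lower in DekTg, and 2593 had an unadjusted p under 0.05. Without the 6 genes that hold values that are not whole, 8 genes passed, 7 higher and 1 lower. Without DekTg replicate 2, 21 genes passed, 10 higher and 11 lower, among them all 13. EdgeR on the recovered reads called 9 genes, among them all 8 left without those 6 genes. DESeq2 called 15 genes, 4 higher and 11 lower, and shared 2 with the 8, Igkc and Phactr2. Its independent filtering left 3510 genes with an adjusted p, and the other 6 of the 8 were not among them. Without that filtering DESeq2 called 11 genes, 6 higher and 5 lower, among them 6 of the 8, all but the variable segments Igkv14-126 (adjusted p = 0.17) and Ighv11-2 (0.631). Groups did not overlap for 1486 genes, or 3.97% of those tested, where chance gives 2.86%. That chance share takes the 8 libraries as separate samples, and is larger if libraries 1 and 4 of a group are not.

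**Figure D1:**
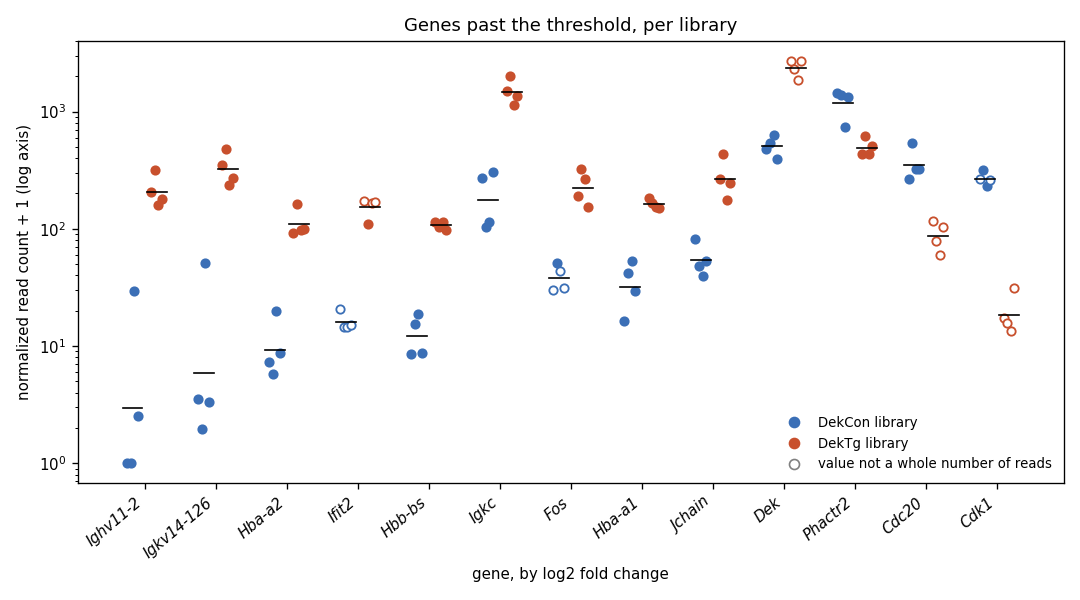
Normalized read count + 1 on a log axis for the 13 genes past the threshold, with 1 point per library (blue, DekCon; red, DekTg), a bar at the mean of the log values, and open points for values that are not whole numbers of reads. The 4 DekTg points lie on 1 side of the 4 DekCon points for each gene, and open points occur in Dek, Ifit2, Fos, Cdc20 and Cdk1.

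Among genes with whole values, the transcripts that rose were those of hemoglobin and of immunoglobulin. The adult alpha-globin gene Hba-a2 rose from 9.42 ± 6.40 to 112 ± 34 (SD, n = 4 each; log2 fold change 3.57, SE 0.33, adjusted p = 3.03e-05). Hba-a1 rose from 34.2 ± 15.8 to 162 ± 14 (2.34, SE 0.27, adjusted p = 0.000515), and the beta-globin gene Hbb-bs rose from 11.9 ± 5.1 to 106 ± 8 (3.14, SE 0.26, adjusted p = 9.53e-06). The alpha genes are near-identical copies on chromosome 11, so reads may not be assigned securely between them. Hemoglobin reads together made up 28.1 ± 7.2 per 1000000 reads in DekCon and 152.5 ± 14.4 in DekTg (SD, n = 4 each).

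The kappa constant gene Igkc rose from 197 ± 104 to 1496 ± 370 (SD, n = 4 each; log2 fold change 3.05, SE 0.29, adjusted p = 3.87e-05). Jchain, which encodes the joining chain of secreted IgM and IgA, rose from 54.8 ± 18.5 to 279 ± 108 (2.31, SE 0.25, adjusted p = 0.00021). The variable segments Igkv14-126 (log2 fold change 5.78, adjusted p = 0.00053) and Ighv11-2 (6.14, adjusted p = 0.000736) complete the calls and lie outside the naming rule. Igkv14-126 averaged 13.9 ± 24.0 in DekCon and 334 ± 108 in DekTg, and Ighv11-2 averaged 7.45 ± 13.90 and 214 ± 70. DekCon replicate 3 carried both DekCon means, with 49.9 and 28.3, against at most 2.54 and 1.54 in the other DekCon libraries. Over the alternatives the log2 fold change ranged from 4.57 to 6.83 for Igkv14-126 and from 4.62 to 7.96 for Ighv11-2. Reads of variable segments can be shared between related segments. With limma's robust option Igkc and both segments were no longer past the threshold, and without the trend these 3, Jchain, Hba-a1 and Hba-a2 were not. Ighv11-2 was also lost with a pseudocount of 0.1, and both segments with DESeq2 without independent filtering.

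Phactr2, a regulator of protein phosphatase and actin, was the 1 gene with whole values that fell, from 1223 ± 324 to 497 ± 85 (SD, n = 4 each; log2 fold change -1.27, SE 0.19, adjusted p = 0.00972). It lies on chromosome 10 from 13207717 to 13474412 on the minus strand. Its call ended in 7 alternatives: without the trend (adjusted p = 0.553), with the robust option (0.128), leaving out DekCon replicate 1 (0.0799), DekCon replicate 4 (0.0693), DekTg replicate 1 (0.0617) or DekTg replicate 3 (0.0799), and averaging libraries 1 and 4 (0.49). Over all its alternatives the adjusted p ranged from 8.33e-08 to 0.553. The next genes lower in DekTg did not pass: Csnk2a1, a catalytic subunit of casein kinase 2, had a log2 fold change of -0.68 (adjusted p = 0.193), Ybx1 of -0.82 (0.195) and Inka1 of -0.85 (0.208). Csnk2a1 passed with the robust option (0.0454), with library weights (0.016), without DekTg replicate 2 (0.0338) and by DESeq2 (0.000367, and 0.00244 without independent filtering), and its adjusted p reached 0.889 under other alternatives. Ybx1 passed with library weights (0.0267), with the replicate number as a block (0.0277) and by DESeq2 (0.00112, and 0.00828 without independent filtering), and its adjusted p reached 0.889 under others. Inka1 passed by DESeq2 without independent filtering (0.0385).

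The other 4 calls rest on genes that hold values that are not whole. Cdk1, the kinase that drives entry into mitosis, was listed at 267 ± 35 in DekCon and 18.3 ± 8.1 in DekTg (SD, n = 4 each; log2 fold change -3.87, SE 0.23, adjusted p = 2.00e-07), with 6 values that are not whole. Cdc20, an activator of the anaphase-promoting complex, was listed at 360.5 ± 118.7 and 88.4 ± 25.5 (-2.01, SE 0.22, adjusted p = 0.000271), with 4 such values, all in DekTg; it overlaps Elovl1 on the other strand. The interferon-induced Ifit2 was listed at 15.3 ± 3.0 and 153 ± 30 (3.23, SE 0.21, adjusted p = 3.86e-07), with 7 such values. The immediate early transcription factor Fos was listed at 37.8 ± 9.99 and 232 ± 77 (2.56, SE 0.23, adjusted p = 2.70e-05), with 3 such values, all in DekCon. Without the trend Fos (adjusted p = 0.0513) and Cdc20 (0.189) did not pass, and Cdk1 and Ifit2 passed in all 20 alternatives run. All 20 reuse the values that are not whole, and the runs that leave these genes out are not among them. Passing them is therefore no support for these calls.

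**Figure D2:**
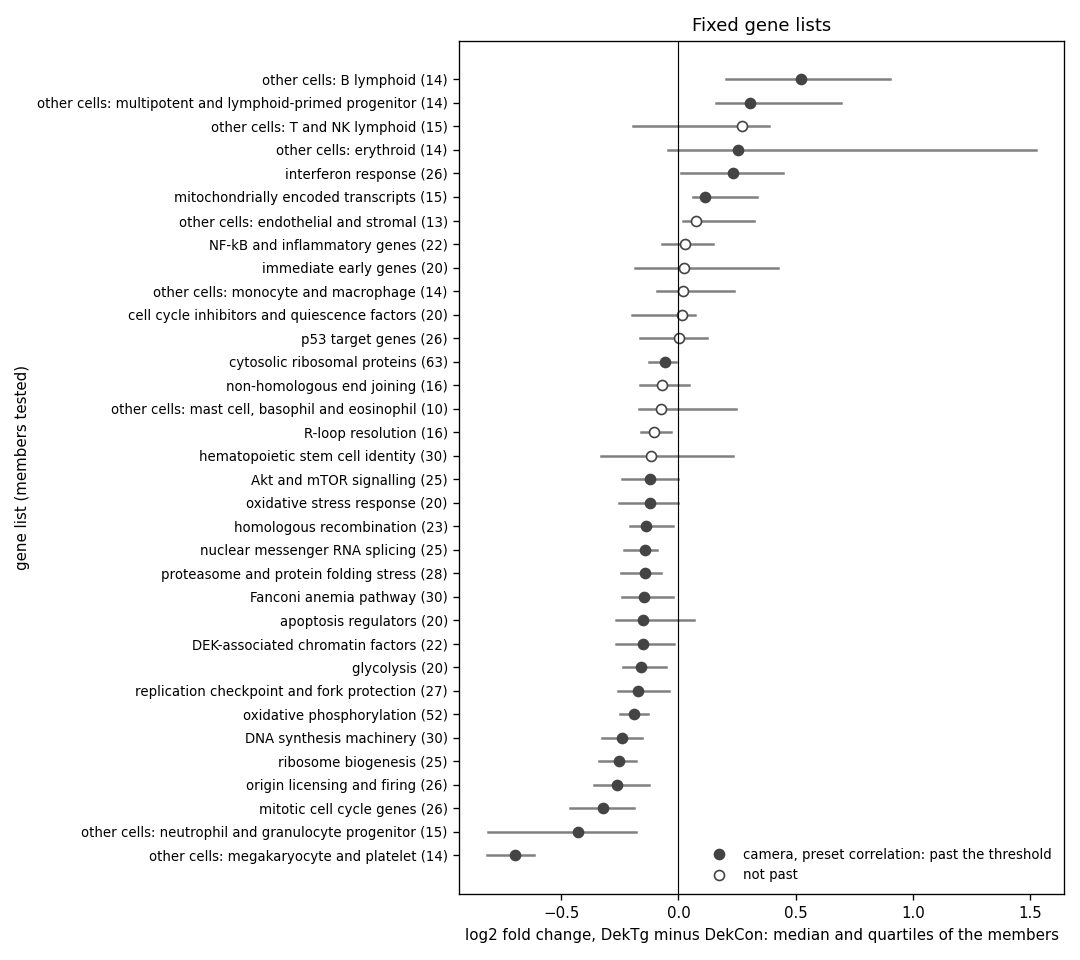
Median log2 fold change, DekTg minus DekCon (point), with the quartiles of the members (line), for the 34 gene lists tested; filled points mark lists past the threshold with camera's preset correlation. The megakaryocyte list has the lowest median (-0.70) and the B lymphoid list the highest (0.52).

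Gene lists past the threshold numbered 23 of 34 with camera's preset correlation of 0.01. Splits of the libraries with 2 of each group on each side gave up to 20, so adjusted p-values with the preset correlation overstate the evidence. With an estimated correlation none passed (smallest adjusted p = 0.114, for B lymphoid genes), nor did any by fry (smallest adjusted p = 0.0583). Without DekCon replicate 2, a library that differs from the other 7, 15 lists passed. With quantile normalization the lists of Fanconi anemia, homologous recombination, checkpoint, apoptosis, DEK-associated factors, glycolysis, proteasome, oxidative stress, splicing and Akt and mTOR did not pass. With edgeR those of Fanconi anemia, apoptosis, oxidative stress, Akt and mTOR, ribosomal proteins and neutrophils did not. With DESeq2 after independent filtering 6 of the 23 passed, and the erythroid and B lymphoid lists, among the 23, were not tested. Oxidative stress also failed without limma's trend, and it and the neutrophil list failed with libraries 1 and 4 averaged. Values without that library are given with each group of lists, with those of other libraries whose removal changes a call. Of 78 named genes other than Dek, 32 moved by over 1.5 times or changed sign on leaving out 1 library, and 0 of these are called genes. Without DekCon replicate 2 the log2 fold change was -0.42 for Bcl2l1, -0.38 for Faap24, -0.15 for Usp1, -0.22 for Gpx4, -0.28 for Nkg7, -0.23 for Nop56, -0.18 for Psmd2, -0.21 for Rfc2, -0.14 for Rnaseh2a, -0.31 for Timeless, -0.10 for Poll, 0.51 for Dntt, -0.57 for Mpo, -0.76 for Gp5, -0.46 for Itga2b, 0.11 for Irf8, 0.41 for Cd4 and 0.35 for Sparc. Without DekTg replicate 2 it was -0.28 for Rps6kb2, -0.06 for Poll, -0.14 for Rnaseh2a, 0.39 for Irf8 and -0.40 for Rpl35. Other moves were Xrcc6 to -0.10 and Rpl35 to -0.15 without DekTg replicate 4, Btg2 to -0.18 without DekTg replicate 1, and Adgre1 to 1.38 and Txnip to 0.15 without DekCon replicate 3.

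Genes of DNA replication and of mitosis lay slightly lower in DekTg. Most lists of growth and metabolism below did so too, so the fall was not particular to these genes. Summed normalized counts ran from 2.96e+06 to 3.17e+06 in DekTg and from 3.08e+06 to 3.52e+06 in DekCon, while the median log2 fold change of all genes tested was 0.0057. The main setting does not separate these lists from a general fall of well-expressed genes. In the DNA synthesis list, 0 of 30 members had a fold change above 0, and the median log2 fold change was -0.24 (camera adjusted p = 1.63e-08, and adjusted p = 0.353 with an estimated correlation). No member passed alone. Pold2, a subunit of DNA polymerase delta, had -0.56 and the clamp loader subunit Rfc2 had -0.33. The list of origin licensing and firing had 3 of 26 members above 0 and a median of -0.26 (adjusted p = 4.10e-07, and 0.353 with an estimated correlation), with Gins2 at -0.38 and Cdc6 at -0.56. Of 26 mitotic genes, 2 were lower, Cdk1 and Cdc20, and 24 did not pass. Adjusted over the list alone 3 were lower, the other being Nek2 (-0.75). Their median was -0.32 (adjusted p = 4.62e-12, and 0.353 with an estimated correlation), and -0.29 over the 24 members left without Cdk1 and Cdc20 (adjusted p = 6.78e-08, and 0.376 with an estimated correlation). The list of replication checkpoint and fork protection had a median of -0.17 (adjusted p = 0.000791, and 0.355 with an estimated correlation), with Timeless at -0.48 and Blm at -0.45. Without DekCon replicate 2 the mean log2 fold change of the DNA synthesis list moved from -0.26 to -0.12, of the origin list from -0.24 to -0.11 and of the mitotic list from -0.53 to -0.31, and the checkpoint list no longer passed (adjusted p = 0.128).

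Lists of DNA repair and damage response were tested as well. For the Fanconi anemia pathway, 0 of 30 members passed, 6 lay above 0 and the median was -0.15 (camera adjusted p = 0.00967, and adjusted p = 0.382 with an estimated correlation). It did not pass without DekCon replicate 2 (0.36, mean moved from -0.14 to -0.05) or DekTg replicate 1 (0.0991), nor with quantile normalization, edgeR or DESeq2 with independent filtering. Its members of smallest p were Faap24 at -0.59 and Usp1 at -0.27. Homologous recombination had a median of -0.14 (adjusted p = 0.00457, and 0.355 with an estimated correlation), with Swsap1 at -0.71 and Rad51d at -0.30, and did not pass without DekCon replicate 2 (0.128) or DekTg replicate 1 (0.0622). Non-homologous end joining (median -0.07, adjusted p = 0.288; Xrcc6 -0.21, Poll -0.24), R-loop resolution (-0.10, 0.0642; Srsf1 -0.24, Rnaseh2a -0.25) and p53 targets (0.00, 0.885; Pmaip1 0.67, Btg2 -0.29) did not pass, except R-loop resolution without DekCon replicate 3 (0.0135), DekCon replicate 4 (0.0461) or DekTg replicate 2 (0.0201) and with DESeq2 without independent filtering (0.0234). Apoptosis regulators had a median of -0.15 (adjusted p = 0.0216, and 0.353 with an estimated correlation), with the anti-apoptotic Bcl2l1 at -0.68 and Pmaip1 at 0.67, and did not pass without DekCon replicate 2 (0.121) or DekTg replicate 3 (0.0959). Cell cycle inhibitors and quiescence factors did not pass (median 0.02, adjusted p = 0.513; Cdkn2d -0.34, Txnip 0.25).

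Lists of growth and metabolism were mostly lower. Ribosome biogenesis had 0 of 25 members above 0 and a median of -0.26 (camera adjusted p = 2.80e-08, and adjusted p = 0.353 with an estimated correlation), with the nucleolar proteins Nop56 at -0.35 and Nhp2 at -0.40. Nuclear-encoded oxidative phosphorylation had 2 of 52 above 0 and a median of -0.19 (adjusted p = 7.70e-09, and 0.355 with an estimated correlation), with Uqcrc1 at -0.61 and Ndufb7 at -0.58. Transcripts of the mitochondrial genome went the other way, with 14 of 15 above 0 and a median of 0.11 (adjusted p = 0.000478, and 0.355 with an estimated correlation), mt-Nd5 at 0.34 and mt-Atp8 at 0.39. Their mean of 0.20 moved to 0.32 without DekCon replicate 2, 0.10 without DekCon replicate 3 and 0.31 without DekTg replicate 3, and passed in each case. Glycolysis had a median of -0.16 (adjusted p = 0.00401, and 0.364 with an estimated correlation), with Hk2 at -0.42 and Slc2a3 at -0.30, and did not pass without DekTg replicate 2 (0.104). Cytosolic ribosomal proteins had a median of -0.06 (adjusted p = 0.0119, and 0.676 with an estimated correlation), with Rps18 at -0.27 and Rpl35 at -0.26, and with quantile normalization their mean turned to 0.0775. They did not pass without DekTg replicate 3 (0.412) or DekTg replicate 4 (0.385), and their mean of -0.07 moved to -0.13 without DekCon replicate 1 and -0.15 without DekTg replicate 2. Proteasome and folding stress (-0.14, adjusted p = 0.000478; Herpud1 -0.38, Psmd2 -0.28), oxidative stress (-0.12, 0.018; Srxn1 0.53, Gpx4 -0.38), splicing (-0.14, 0.00035; Srsf2 -0.50, Snrnp70 -0.32) and Akt and mTOR signalling (-0.12, 0.0109; Eif4ebp1 -0.45, Rps6kb2 -0.66) passed with the preset correlation. With an estimated correlation their adjusted p lay between 0.353 and 0.382, and none of these 4 lists, nor the ribosomal proteins, passed without DekCon replicate 2 (adjusted p = 0.128 for proteasome, 0.168 for oxidative stress, 0.11 for splicing, 0.0729 for Akt and mTOR and 0.981 for ribosomal proteins). The Akt and mTOR list also failed without DekCon replicate 1 (0.0508) or DekTg replicate 1 (0.0612), and oxidative stress without DekTg replicate 1 (0.123), DekTg replicate 3 (0.0707) or DekTg replicate 4 (0.108), while its mean of -0.11 moved to -0.18 without DekTg replicate 2. The mean of ribosome biogenesis moved from -0.27 to -0.12 without DekCon replicate 2, and that of oxidative phosphorylation from -0.20 to -0.10.

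Of DEK-associated chromatin factors, 0 of 22 passed over all genes and 1 was lower adjusted over the list alone, Csnk2a1. The list's median was -0.15 (camera adjusted p = 0.000189, and adjusted p = 0.353 with an estimated correlation), with the histone chaperone Daxx at -0.63. Its mean moved from -0.19 to -0.11 without DekCon replicate 2 (adjusted p = 0.0203), and the list did not pass with quantile normalization or with DESeq2 after independent filtering. Of 26 interferon response genes, 1 was higher, Ifit2, and 2 adjusted over the list alone, the other being Ifit3 (1.06). Their median was 0.23 (adjusted p = 3.82e-05, and 0.353 with an estimated correlation), and 0.19 over the 25 members without Ifit2 (adjusted p = 0.00152, and 0.376 with an estimated correlation). Of 20 immediate early genes, 1 was higher, Fos, both over all genes and over the list alone, and the list did not pass (median 0.02, adjusted p = 0.14), except without DekCon replicate 4 (0.0191). NF-kB and inflammatory genes did not pass (0.03, 0.47; Ccl3 1.49, Nfkbia -0.41). Ccl3 was 0 in DekCon replicate 2 and moved to 0.61 without it and to 2.34 with a pseudocount of 0.1, and Nfkbia moved to -0.22 without DekTg replicate 2. The list of hematopoietic stem cell identity did not pass either (-0.12, 0.0649), and passed without DekCon replicate 2 (adjusted p = 0.0189) or DekCon replicate 3 (0.043), with library weights (0.0172), with the replicate number as a block (0.02975), with a term for libraries 1 and 4 (0.0452) and with DESeq2 without independent filtering (0.00105). Its member Slamf1 had -0.40.

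Markers of other cell types were tested as lists too. Of 14 erythroid genes, 3 were higher (the hemoglobin genes above) and 4 adjusted over the list alone, the other being Hbb-bt (1.66). The list's median was 0.25 (camera adjusted p = 1.50e-05, and adjusted p = 0.353 with an estimated correlation). Erythroid members other than hemoglobin went both ways, with Slc4a1 at 1.13 and Klf1 at -0.89. Of 14 B lymphoid genes, 2 were higher, Igkc and Jchain, and 4 adjusted over the list alone, with Ighm (3.82) and the B cell transcription factor Pax5 (0.89). The median was 0.52 (adjusted p = 6.55e-08, and 0.114 with an estimated correlation). All 14 members of the multipotent and lymphoid-primed list lay above 0, with a median of 0.31 (adjusted p = 7.82e-06, and 0.353 with an estimated correlation). None passed over all genes, and Ighm passed over the list alone. Dntt, the terminal transferase of early lymphoid cells, had 2.14. In DekCon replicate 2, Dntt was 4.78 and Ighm 14.4, against at least 323 and 362 in the other DekCon libraries, and without it the list's mean moved from 0.75 to 0.30. Ighm passed over all genes without that library (log2 fold change 2.59, adjusted p = 3.98e-07) and with the term for libraries 1 and 4 (0.0479), against at most 0.73 under other alternatives.

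Megakaryocyte and platelet genes lay lower in DekTg, with 0 of 14 above 0 and a median of -0.70 (camera adjusted p = 7.12e-10, and adjusted p = 0.353 with an estimated correlation). None passed over all genes, and 6 were lower adjusted over the list alone, among them Gp5 at -1.13 and the integrin gene Itga2b at -0.83. Without DekCon replicate 2, where Itga2b was 3859, the mean of the list moved from -0.67 to -0.38. Neutrophil and granulocyte progenitor genes had a median of -0.43 (adjusted p = 0.00759, and 0.465 with an estimated correlation). That list did not pass without DekCon replicate 3 (0.147), and without DekTg replicate 1 (0.42) or DekTg replicate 4 (0.568) its mean of -0.34 turned to 0.03 and 0.08. Its mean was -0.54 without DekCon replicate 1 and -1.04 without DekTg replicate 3. Prtn3, at -0.47, was lower adjusted over the list alone and passed over all genes by DESeq2 (0.0299, range over alternatives 0.0299 to 0.889), and Mpo, at -0.90, passed with the term for libraries 1 and 4 (0.0285, range 0.0285 to 1). Monocyte and macrophage genes (median 0.02, adjusted p = 0.438; Adgre1 0.89, Irf8 0.26), T and NK genes (0.27, 0.27; Nkg7 -0.50, Cd4 0.68), mast cell, basophil and eosinophil genes (-0.07, 0.815; Prss34 1.94, Fcer1a -0.60) and endothelial and stromal genes (0.08, 0.112; Col3a1 -0.67, Sparc 0.66) did not pass. Prss34 and Fcer1a passed over their list alone, in opposite directions, Prss34 passed over all genes without DekTg replicate 3 (0.0118, range 0.0118 to 0.889), and the mast cell list's median and mean (0.17) differ in sign. The monocyte list passed, higher, without DekCon replicate 3 (0.0442).

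Of the genes of the sort gate, Slamf1, which encodes CD150, was 268 ± 31 in DekCon and 201.3 ± 12.3 in DekTg (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.114 over the 4 markers), and lower adjusted over the list alone with limma. The log2 fold change was 0.01 for Kit, 0.30 for Ly6a and 0.14 for Cd48, which the gate excludes as a protein and whose transcript averaged 195 ± 62 and 207 ± 26. Leaving out 1 library changed the sign for Kit (-0.08 without DekCon replicate 3, -0.07 without DekTg replicate 2) and Cd48 (-0.04 without DekCon replicate 2), and Ly6a moved to 0.09 without DekCon replicate 2, 0.19 without DekCon replicate 3 and 0.48 without DekCon replicate 1. Y-linked transcripts were present in all 8 libraries, with Kdm5d at 140.2 ± 3.6 and 115 ± 9, Ddx3y at 448 ± 54 and 365 ± 87, Eif2s3y at 241 ± 16 and 228 ± 25 and Uty at 225 ± 24 and 226 ± 18, beside Xist at 29.5 ± 9.7 and 25.4 ± 5.4.

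**Figure D3:**
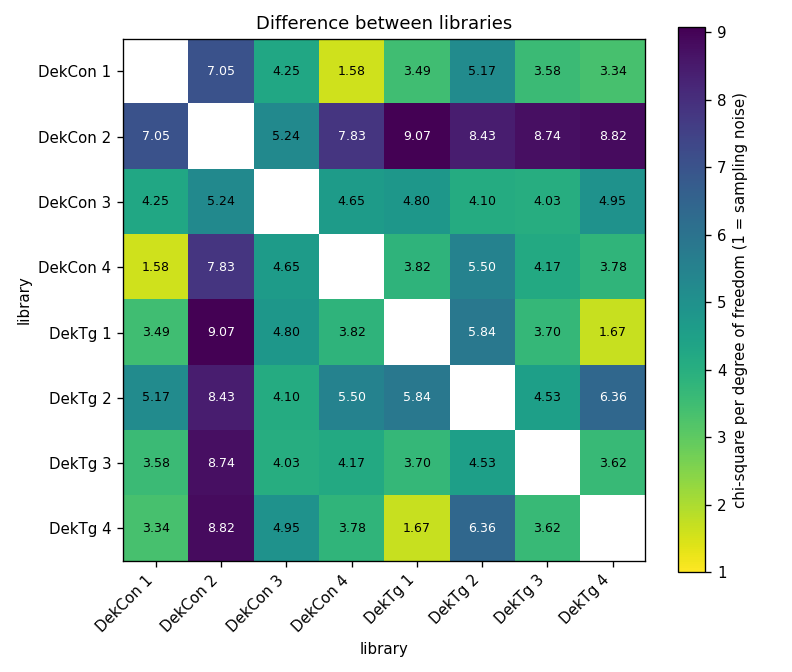
Chi-square per degree of freedom between the recovered reads of each pair of libraries, over genes with at least 20 reads in the pair; 1 is the level of sampling noise. Libraries 1 and 4 stand at 1.58 in DekCon and 1.67 in DekTg, and the other 26 pairs between 3.34 and 9.07.

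Libraries were not equally far apart. The chi-square per degree of freedom of recovered reads was 1.58 between DekCon replicates 1 and 4 and 1.67 between DekTg replicates 1 and 4. The other 10 pairs within a group stood between 3.62 and 7.83, and the 16 pairs across groups between 3.34 and 9.07. The close pairs differed by more than sampling noise, which amplified libraries of the same RNA would also do, so this does not show that they are separate samples. They were counted as separate libraries, as labelled, and n = 4 per group rests on that. With libraries 1 and 4 of each group averaged, 12 genes passed, all of them among the 13, and Phactr2 was lost. The first principal component held 18.7% of the variance and the second 17.2%. The first mainly set DekTg replicate 2 apart (score 110.9) and the second DekCon replicate 2 (-110.6). These libraries also had the lowest weights in the weighted fit, 0.544 for DekTg replicate 2 and 0.649 for DekCon replicate 2.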

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

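The tests weighed here were chosen after the result was seen, except those of the late erythroid and plasma cell markers, of leaving out 1 library and of the estimated correlation, and the minimum of 50 reads for segments was chosen after some of those reads were seen. A library lay far from the other 3 of its group in 16 of 166 groups of values, where chance gives about 8.3. Among called genes, Hba-a2 was 162.2 in DekTg replicate 2 against at most 98.7 in the others, Ifit2 was 19.87 in DekCon replicate 1 against at most 14.2 and 108.1 in DekTg replicate 2 against at least 165, and Phactr2 was 740.6 in DekCon replicate 3 against at least 1338. DekCon replicate 2 stood out with Bcl2l1 at 1069, Srsf2 at 2861, Ighm at 14.35 and Dntt at 4.785. DekTg replicate 2 stood out with Poll at 78.08, Srsf1 at 460.0, Rps6kb2 at 30.03, Uqcrc1 at 490.1 and Itga2b at 724.3. The remaining values were mt-Atp8 at 358.8 in DekCon replicate 1, Kit at 1072 in DekCon replicate 3 and Ighm at 3636 in DekTg replicate 3.

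Hemoglobin and immunoglobulin transcripts were higher in all 4 DekTg libraries, although the gate should remove erythroid and plasma cells. A single immunoglobulin source as the whole cause is argued against: the leading heavy variable segment was Ighv1-64 in 2 DekTg libraries (321 and 246 reads, with 0 and 1 in the others) and Ighv11-2 in the other 2, although Ighv11-2 occurred in all 4 and Igkv14-126 led the kappa segments in all 4, so a shared source for part of the rise stays open. The 10 late erythroid markers had a median log2 fold change of -0.152 (95% bootstrap interval -0.37 to -0.04), which met the bound set beforehand for excluding erythroid RNA; that bound was judged wrong after the result was seen, because all 10 markers were present in DekCon (highest mean 7510, Ubb) and their median level of 264 exceeds the median hemoglobin rise of 103. RNA of erythroid cells therefore cannot be told apart from a change in the stem cells. The 10 plasma cell markers cannot decide either, but for another reason. Their level in DekCon is low (median 31.3, against a median rise of 762 for Igkc and Jchain), which does not void the test. They went both ways, with 5 above 0, and the interval of their median of -0.015 spans 0 (-0.24 to 0.33). Of variable segments with at least 50 reads in either library, 2 of 10 reached that in both DekTg replicates 1 and 2, and 4 of 8 in both replicates 1 and 3. If a change common to DekTg stem cells raised variable segments, it should raise the same ones in each library, a premise not tested here. On that premise, the segments not shared argue against such a change as the whole cause of the immunoglobulin rise. The shared ones do not decide. Ighv11-2 and Igkv14-126 also had 30 and 53 reads in DekCon replicate 3, so they are not particular to DekTg. An effect of the DekTg genotype stays open and was not tested.

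The 25 values that are not whole are confined to 6 genes, of which 5 are among the 13 calls. Rounding of the table would leave distances as small as in other genes, at most 5.0e-05 reads, but the smallest distance among the 25 is 0.0107. Counting shared reads in fractions would touch other genes, and 0 other genes have such a value. The same distance from a whole read recurs between genes of a library, 0.334 for Cdc20, Cdk1 and Ifit2 in DekTg replicate 1 and 0.245 for Cdk1 and Ifit2 in DekTg replicate 4. In DekTg replicate 1 it lay below a whole read for Cdc20 and Cdk1 (139.666 and 19.666 reads) and above for Ifit2 (209.334). In DekTg replicate 4 it lay below for Cdk1 (28.755) and above for Ifit2 (160.245), and Cdc20 did not share it (0.294). Values that recur in this way are tied to each other within a library, so they cannot be read as separate counts of each gene. Adding the same amount to whole reads of Ifit2 and taking it from those of Cdk1 would leave such mirrored distances. In DekTg replicate 1 the same holds for Cdc20 as for Cdk1. Shifts of that kind go in the direction of these genes' calls, so their fold changes cannot be taken as measured. How these values were made is not recorded in the sources used here, and no biological explanation was tested.

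Libraries 1 and 4 of each group were closer than any other pair. A single library deposited in duplicate would differ by sampling noise only, whereas the lower of the 2 values was 1.58 (chi-square per degree of freedom). A candidate explanation is that both were made from the same cells or RNA, since all 6 immunoglobulin variable segments with at least 50 reads in DekTg library 1 or 4 reached 50 reads in both, against 2 of 10 for DekTg libraries 2 and 3 and 4 of 8 for library 3 with 1 or with 4. Since 4 of the 6 also reached 50 reads in library 3, only Igkv5-48 and Ighv1-64 were particular to libraries 1 and 4. In DekCon 0 of 3 reached 50 reads in both libraries 1 and 4 (and 0 of 1 in 2 and 3), but the 3 occurred in both at 42 and 72 (Igkv17-121), 38 and 56 (Ighv1-72) and 24 and 66 reads (Igkv15-103), against at most 3 reads in DekCon libraries 2 and 3; no biological explanation was tested.

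Chance could not be excluded for the counts of genes. Of 35 splits of the 8 libraries into 4 and 4, 2 gave as many genes as the real one, with 13 in the real split and 35 in the highest other. That other split sets libraries 1 and 4 of both groups against libraries 2 and 3, and points to a structure of the samples; the next split gave 5 genes. For genes higher in DekTg, 2 splits gave as many as the real 10 (highest other 18), and for genes lower, 3 gave as many as the real 3 (highest other 18). Direction has no meaning in the other splits, so their direction with more genes was taken. These counts of splits include the real one. Without the 6 genes, 2 splits gave as many as the real 8 (highest other 35). With a term for libraries 1 and 4 against 2 and 3, the DekTg comparison called 18 genes, among them all 13. For gene lists, 1 of 35 splits, the real one with 23, gave as many (highest other 21). That would exclude chance only if the 8 libraries are separate samples, which the closeness of libraries 1 and 4 leaves open, so chance is not taken as excluded. Leaving out 1 library moves the real count between 15 and 25, and 0 lists pass with an estimated correlation. Splits with 2 libraries of each group on each side, where the groups are balanced, gave from 0 to 20 lists. The preset correlation thus called many lists without a difference between the groups.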

How the results depend on the processing

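Alternatives on recovered reads, with libraries 1 and 4 averaged, with a term for them or without the 6 genes were chosen after seeing the data. The Dek log2 fold change stayed between 2.09 and 2.39 and past the threshold under each alternative run (adjusted p at most 0.0368). Count tools left Dek out, and each alternative run for Dek reuses its values that are not whole, so passing them is no support for the Dek call. The cause of the following moves was not tested unless stated. The count of 13 genes became 4 without limma's trend (3 higher, 1 lower). These were Dek, Ifit2, Cdk1 and Hbb-bs, and of them only Hbb-bs has whole values in every library. The count became 8 without the 6 genes (1 lower), by construction. DESeq2 gave 4 higher and 11 lower, without independent filtering 6 and 5, and edgeR 1 lower. Genes lower numbered 6 with library weights and 7 with the term for libraries 1 and 4. With the replicate block 15 genes passed, 10 higher and 5 lower, all 13 among them. Same-numbered libraries deviated together with correlations of 0.03, 0.01, 0.04 and 0.16, so little pairing by number was seen. Shared preparation is not excluded, since the split of libraries 1 and 4 of both groups against 2 and 3 gave 35 genes. Leaving out 1 library gave 13 to 21 genes, 10 to 12 higher and 2 to 11 lower (21 and 11 without DekTg replicate 2), and 15 to 25 lists. In place of 23 lists, 13 passed with quantile normalization, 6 with DESeq2 (25 without independent filtering), and 0 with an estimated correlation and 0 by fry. DESeq2 with independent filtering did not test the erythroid and B lymphoid lists. The mean of the cytosolic ribosomal proteins reversed to 0.0775 with quantile normalization (adjusted p = 0.000242), and leaving out 1 library it ranged from -0.151 to -0.00304, where camera turned upward without DekCon replicate 2. The neutrophil list reversed to 0.32 with edgeR and ranged from -1.04 to 0.0753 leaving out 1 library. With DESeq2, against the 3510 genes its filtering left, camera turned upward, not past the threshold, for the Fanconi anemia (mean -0.13), checkpoint (-0.18), Akt and mTOR (-0.12) and ribosomal protein (-0.0683) lists, whose means stayed below 0. Named genes other than Dek kept their side of the threshold in 1783 comparisons, lost it in 21 and gained it in 15; lists did so in 762, 95 and 12, and 9 reversed. At these depths values near 1 stand for 1 or 2 reads.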

Other observations

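The immunoglobulin transcripts of the DekTg libraries were dominated by few variable segments, and were read out after the calls were seen. Among kappa segments, Igkv14-126 led in all 4 DekTg libraries with 34.1 to 41.5% of the reads of its family, and it led in 1 of 4 DekCon libraries, replicate 3, with 14.8%. Among heavy segments, Ighv11-2 had 248, 262, 162 and 171 reads in DekTg replicates 1 to 4 and 0, 0, 30 and 2 in DekCon replicates 1 to 4. Ighv11-2 and Igkv14-126 are known as the paired segments of a phosphatidylcholine-binding receptor of B-1a cells, a self-renewing B cell class. Some other segments had most of their reads in 1 library, such as Ighv4-1 with 184 reads in DekTg replicate 2 (at most 2 in the others) and Ighv10-3 with 99 in DekTg replicate 3 (at most 3 in the others). Others were shared across both groups, such as Igkv15-103 with 24 and 66 reads in DekCon replicates 1 and 4 and 209, 139 and 143 in DekTg replicates 1, 3 and 4.

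The constant genes differed in pattern as well. Ighm was 358 ± 243 in DekCon and 2834 ± 535 in DekTg (SD, n = 4 each; limma adjusted p = 0.208), and Ighg1 was 937, 1640 and 1072 in DekTg replicates 1, 2 and 4 but 15.5 in DekTg replicate 3 and at most 34.9 in DekCon. Ighg1 was called by edgeR (log2 fold change 5.40, adjusted p = 0.0467) and DESeq2 (5.40, 0.000211, and 0.0012 without independent filtering) and not by limma (4.27, 0.389). Ighg2b went the other way, at 366 and 398 in DekCon replicates 1 and 4, 4.78 and 24.5 in replicates 2 and 3, and at most 42.0 in DekTg. Igha reached 602 in DekTg replicate 2 and at most 32.1 in the other 7 libraries. Immunoglobulin reads together were 479 ± 181 per 1000000 reads in DekCon and 2368 ± 362 in DekTg.

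Of 12 genes within 1000000 bases of Phactr2, chosen after its call, none passed the threshold (limma, smallest adjusted p = 0.763). The 8 with a DekCon mean of at least 50 had log2 fold changes from -0.42 (Stx11) to 0.11 (Hivep2).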
